A study of Mus musculus with 18 samples.

How the data were processed

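RNA sequencing was done on 18 libraries from mouse bone marrow and bone marrow-derived dendritic cells (BMDCs), the antigen-presenting cells grown from marrow in culture. Per the labels, the libraries fall into 6 groups of 3: wild-type (WT) C57BL/6 and FAT1 transgenic mice, each as day 0 bone marrow, as immature BMDCs without treatment and as mature BMDCs, whose titles name LPS (bacterial lipopolysaccharide, a Toll-like receptor ligand) and gp100 (an antigen of melanocytes and melanoma). The labels call all 18 libraries BMDCs, and the design text of the series calls the day 0 group bone marrow, which is the name used here. Per the labels, the molecule was total RNA, extracted with a Zymo Research kit. Culture conditions, doses, times, the library kit, read length and strandedness are not given in the sources used here.

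The authors deposited 1 table of RSEM expected counts and 1 table of RSEM TPM (a unit scaled for gene length and library), each with 55450 genes and 1 column per library, so replicates were not pooled. Expected counts are estimated counts that divide reads mapping to several genes between them. RSEM and the mm10 build are named per the submitters' processing notes. The RSEM version, the aligner and the annotation are not given in the sources used here. All 55450 gene identifiers with their versions occur in the GENCODE M21 annotation, from which gene types and coordinates (mm10, 1-based) were taken. The deposited TPM values sum to the same total in each library by construction and carry no depth. The deposited metadata table gives an identifier of the animal for each library. It names 3 WT animals and 3 FAT1 animals, each of which gave 1 library at each of the 3 stages. All columns matched a sample by name. Of the expected counts, 6.29% were not whole, and all were rounded to whole numbers before testing.

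The depth was 13219801 to 24304918 expected counts per library, over all genes. Every gene had a name, so nothing was left out of this depth. Genes with too few counts were removed with filterByExpr by group at a minimum count of 10, which left 16738 genes. The library sizes used for scaling and for the main test were then taken over these genes alone. Levels are given as CPM, counts relative to the effective library size, scaled with the trimmed mean of M values (TMM), as mean ± SD of 3 libraries. A fold against a group with 0 counts is given as a lower bound, with 3 counts over that group put in place of 0. A fold against a group with 1 to 3 counts is given as a ratio with a 95% exact binomial interval. Intervals and floors of this kind cover counting error only.

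The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the 6 group means of all 18 libraries, with 12 residual degrees of freedom. P values were adjusted by the Benjamini-Hochberg method over the 16738 genes of a comparison, with a threshold of 0.05. Adjusted p for single genes means this test throughout. There were 9 comparisons: FAT1 against WT at each of 3 stages, immature BMDCs against bone marrow and mature against immature BMDCs in each genotype, and the interaction of genotype with each of these 2 steps. Standard errors (SE) are those of the log2 fold change, except that the SE of a mean or median over genes is from the spread over those genes. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 3 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 297 tests, that is 33 lists in 9 comparisons. Adjusted p for a list means camera unless another test is named. No call of a list was kept with an estimated correlation between genes, and that p is printed beside each call.

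The 33 lists were fixed beforehand. They hold 554 genes, of which 11 are in more than 1 list. The 21 functional lists cover MHC class II presentation, MHC class I presentation, costimulation and migration of dendritic cells (DCs), inhibitory and regulatory DC genes, inflammatory cytokines and chemokines, the type I interferon response, TLR and NF-kB signalling, anti-apoptotic genes, pro-apoptotic genes, eicosanoid and oxylipin synthesis, fatty acid synthesis and desaturation, cholesterol synthesis and uptake, PPAR targets and fatty acid oxidation, oxidative phosphorylation, glycolysis, the antioxidant and NRF2 response, antigen uptake receptors, endoplasmic reticulum stress, the cell cycle, sex-linked transcripts and genes known to differ between C57BL/6 substrains. The 12 marker lists are those of conventional DCs, monocytes and macrophages, neutrophils and granulocyte precursors, erythroid cells, B cells, T and NK cells, megakaryocytes and platelets, mast cells and basophils, eosinophils, stem and progenitor cells, plasmacytoid DCs, and stromal and endothelial cells. Ahsp of the erythroid list has no entry of that name, and 19 other members had too few counts to be tested, among them Il23a, Csf2, Ppara, Xcr1 and the 4 Y-linked genes.

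Genes are named by a rule. For each comparison it takes, among genes with a symbol that is no clone name, past the threshold, at 5 CPM or more in the higher group and with no overlap between the libraries of the groups compared (for an interaction the p and the CPM floor alone), the 6 with the largest rise and the 6 with the largest fall. Immunoglobulin, T cell receptor, mitochondrial and histone genes are left out. It adds up to 4 members past the threshold from each list that passed camera or had 3 or more such members, without a CPM floor. In the comparisons of genotypes, 7 lists on presentation, costimulation, apoptosis, eicosanoids and sex were described whatever they showed, and 16 genes were always taken, though not each gene taken is printed. Where fewer than 6 genes passed, the 6 with the smallest p were taken. For the culture and maturation steps this rule takes well over 100 genes each, so the text names the leading genes and about 2 members of a list. That narrowing was made after the data were seen, as was the choice to name genes outside the rule among those that differed at all 3 stages. The design, the tests, the lists, the rule and the alternatives were set before the data were examined, except where stated.

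The alternatives were DESeq2 1.42.0, RLE size factors in place of TMM, no filter on low counts, edgeR on the groups compared alone, limma on log2(TPM + 1), leaving out each library in turn, and a block. For the steps and the interactions the block was the animal, with 6 levels, and between genotypes it was the replicate number, with 3 levels shared by both genotypes. For lists they were camera with an estimated correlation, fry (which tests whether a list moves one way and does not compare it with other genes), no filter, the block and leaving out each library. Added after seeing the data were limma voom with sample quality weights, which gave the third mature WT library a weight of 0.18, and camera without that library.

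Libraries with the same number within a genotype came from the same animal per the deposited metadata, so the numbers pair the libraries of a genotype across stages. The correlation of deviations from the group means over genes was 0.032 to 0.355 for the same FAT1 animal, above that with either other FAT1 animal (−0.263 to 0.069) in 9 of 9 cases. It was −0.163 to 0.064 for the same WT animal, above both others (−0.157 to 0.15) in 5 of 9. So the values show the pairing in FAT1, while in WT it rests on the metadata. Between genotypes the numbers pair nothing. No replicates were duplicates, as the smallest chi-square per gene between libraries of a group was 5.92. Whether animals of a genotype shared litters or days is not given in the sources used here, so a batch and the genotype cannot be told apart.

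The procedure was tested on simulated counts with 200 changed genes per comparison. For bone marrow (16526 genes) it recovered 52.2%, 67.2% and 83.3% of the genes changed 1.5-fold, 2-fold and 4-fold, with 6 false calls among 141. For immature cells (16526 genes) the shares were 56.7%, 77.6% and 92.4%, with 8 false calls among 159. For mature cells (16563 genes) they were 28.4%, 68.7% and 90.9%, with 6 among 131. For the interaction with culture (16549 genes) they were 10.4%, 53.7% and 81.8%, with 5 among 102. For the interaction with maturation (16544 genes) they were 16.4%, 65.7% and 86.4%, with 2 among 114. In a simulated mature comparison (16553 genes) with a 1.5-fold shift of the MHC class I list, camera gave that list an adjusted p of 1.4e-48 and called 0 of the other lists. The simulated genes were drawn independently of one another, so this cannot show how often camera calls lists of correlated genes falsely. Each simulated gene had the same dispersion in all groups, and no library stood apart from its group as the third mature WT library did. So the shares and false calls simulated for mature cells may not hold for the real mature libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.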

Results

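The transcriptomes of bone marrow, immature BMDCs and mature BMDCs were measured in WT mice and in FAT1 mice, 3 animals per genotype with 1 library per stage. The FAT1 line, on a C57BL/6 background, carries a nematode gene for a desaturase that turns omega-6 into omega-3 fatty acids. The title of the series places the comparison in the study of omega-3 fatty acids, DC lifespan, antigen presentation and DC vaccines. The transgene is no gene of the mouse annotation, so its expression could not be used to check the labels, and mouse Fat1 is an unrelated cadherin. Log2 fold changes are given ± SE, levels in CPM as mean ± SD (n = 3), and adjusted p values from the quasi-likelihood test of edgeR or from camera, with Benjamini-Hochberg adjustment.

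Depth was 13219801 to 18877163 expected counts in bone marrow, 19340240 to 23688828 in immature and 17738534 to 24304918 in mature cells. The first principal component held 76.3% of the variance and parted bone marrow from cultured cells, and the second held 13.7% and parted immature from mature cells. The small cytoplasmic RNA genes Rn7s1 and Rn7s2 took 10.8% to 11.3% of the counts in WT bone marrow and 12.2% to 15.8% in FAT1 bone marrow, against 4.09% to 6.41% in cultured cells. Protein-coding genes took 71.5% to 73.3% of the counts in WT bone marrow, 66.2% to 71.7% in FAT1 bone marrow and 84.1% to 88.7% in cultured cells. The third mature WT library stood apart from its group. It had 18875 genes with a count, against 19809 to 20186 in the other mature libraries, and a score of 68.2 on the third component, against −27.4 to 16.8 elsewhere. Its chi-square per gene was 70.6 and 54 against the other mature WT libraries, where other pairs of mature replicates had 5.92 to 31.1.

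**Figure D1:**
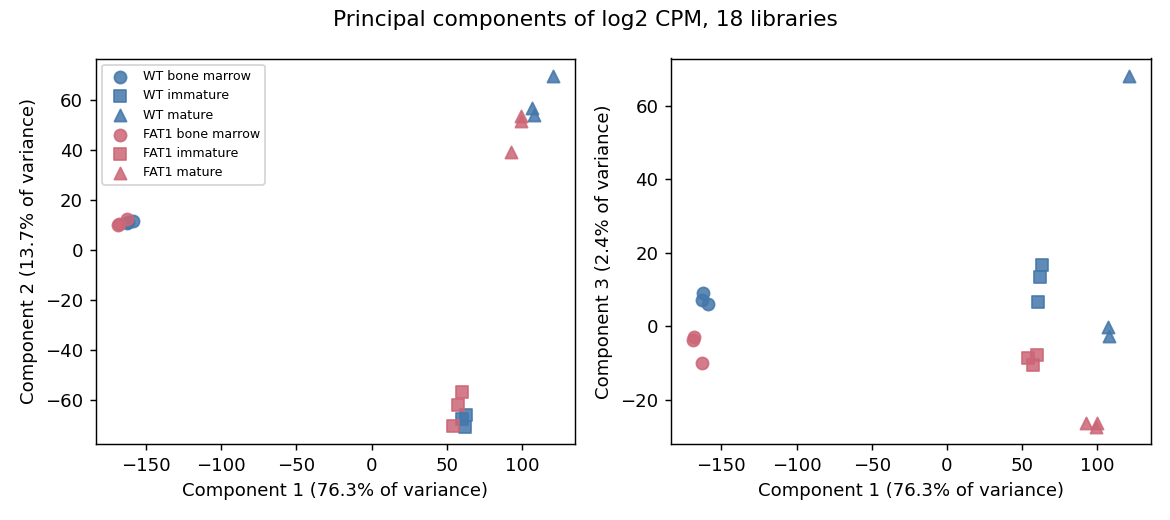
Scores of the 18 libraries on principal components of log2 CPM, in arbitrary units, by genotype and stage. Bone marrow libraries lie apart on the first component (76.3% of the variance), and the third mature WT library lies at 68.2 on the third (2.4%).

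In bone marrow, Tnfaip3 and Nfkbia were higher in FAT1 than in WT mice. Tnfaip3, whose product A20 ends NF-kB signalling, rose from 138 ± 42 to 343 ± 65 CPM (log2 1.31 ± 0.17, edgeR adjusted p = 0.00037). Nfkbia, the inhibitor IkB-alpha, rose from 107 ± 23 to 216 ± 44 CPM (log2 1.02 ± 0.14, edgeR adjusted p = 0.0014). Acod1, the enzyme that makes itaconate, rose from 32.2 ± 9.8 to 93.3 ± 13 CPM (log2 1.54 ± 0.22, edgeR adjusted p = 0.002), and Mid1, a ubiquitin ligase gene on the X chromosome, from 1.19 ± 0.66 to 72.5 ± 39 CPM (log2 5.98 ± 0.49, edgeR adjusted p = 2.8e-06). Pira2, a paired immunoglobulin-like receptor (57.9 ± 0.66 to 24 ± 1.6 CPM, log2 −1.27 ± 0.15), fell. So did the endosomal adaptor Wdfy1, 1 of the 4 substrain genes (41 ± 1.6 to 20.5 ± 1.9 CPM, log2 −0.999 ± 0.13), and the receptor genes Clec2d (log2 −0.97 ± 0.16) and Cd300lb (log2 −0.94 ± 0.15). Over these 4 genes edgeR adjusted p were 0.00012 to 0.0046. Mid1, Pira2 and Dynlt1b (log2 −0.95 ± 0.10, edgeR adjusted p = 6.4e-05) have close copies or overlapping genes among which reads can be divided, so their values are uncertain. In all, 387 of 16738 genes differed, 238 higher and 149 lower in FAT1 marrow.

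Of the 25 tested genes of the TLR and NF-kB list, 4 rose, 0 fell and 21 did not pass, or 8 and 2 adjusted over the list alone. Nfkbie (log2 0.69 ± 0.16) and Nfkbiz (log2 0.60 ± 0.11) rose with Tnfaip3 and Nfkbia, with edgeR adjusted p of 0.035 and 0.0092. The median of the list was 0.09, with a camera adjusted p of 0.0241 (adjusted p = 0.55 with an estimated correlation). This call ended when 1 of 4 libraries was left out, with camera adjusted p of 0.0902 and 0.066 without WT 2 and 3 and of 0.0757 and 0.217 without FAT1 1 and 2. The pro-apoptotic genes Bcl2l11 (BIM; 40.9 ± 2 to 59.3 ± 5.5 CPM, log2 0.53 ± 0.09) and Bbc3 (PUMA; log2 0.86 ± 0.18) rose, with edgeR adjusted p of 0.0039 and 0.019, as did the survival kinase gene Pim1 (log2 0.67 ± 0.16, edgeR adjusted p = 0.042). As sets, the 23 pro-apoptotic genes (2 up, 0 down; 2 and 1 adjusted over the list alone; median −0.09, mean 0.00) and the 15 anti-apoptotic genes (1 up, 0 down, also adjusted over the list alone; median 0.07) did not pass, with camera adjusted p of 0.644 and 0.339.

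The lists of MHC class I and eicosanoid genes were lower on balance in FAT1 marrow. The 21 MHC class I genes had a median log2 fold change of −0.14 with 0 past the threshold, also adjusted over the list alone (camera adjusted p = 0.00143; adjusted p = 0.524 with an estimated correlation). The 19 eicosanoid genes had a median of −0.17 (camera adjusted p = 0.00869; adjusted p = 0.256 with an estimated correlation). Within it Pla2g7, a platelet-activating factor hydrolase (log2 −0.49 ± 0.11), and Lta4h, the last enzyme of leukotriene B4 synthesis (log2 −0.36 ± 0.08), fell, with edgeR adjusted p of 0.029 and 0.026, also adjusted over the list alone. The 23 type I interferon genes had a median of −0.47, with Usp18 (log2 −0.77 ± 0.19, edgeR adjusted p = 0.0497) the 1 that fell, also adjusted over the list alone (camera adjusted p = 0.00313; adjusted p = 0.749 with an estimated correlation). Antigen uptake (20 genes, median −0.25, 0 past the threshold) and glycolysis (18 genes, median −0.17, Pfkp up at log2 0.37 ± 0.08, and 2 up and 4 down adjusted over the list alone) were also lower. Their camera adjusted p were 0.0239 and 0.0202, and adjusted p = 0.548 and 0.665 with an estimated correlation. Cholesterol genes were higher (21 genes, median 0.14, Insig1 up at log2 0.46 ± 0.12 and no other, also adjusted over the list alone; camera adjusted p = 0.0367, adjusted p = 0.655 with an estimated correlation). The calls of uptake, glycolysis and cholesterol each ended without at least 1 library. That was FAT1 3 for uptake (0.139), WT 1 for glycolysis (0.109), and WT 2 and 3 and FAT1 2 and 3 for cholesterol (0.126, 0.0631, 0.338 and 0.0639).

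Markers of marrow cell types moved with these groups. Erythroid markers were higher in FAT1 marrow (14 genes, median 0.39). Markers of monocytes (16 genes, median −0.30), neutrophils (17, −0.45), T and NK cells (15, −0.43) and eosinophils (9, −0.88) were lower. Over the 5 lists camera adjusted p were 4.09e-05 to 0.0033, and adjusted p = 0.202 to 0.502 with an estimated correlation. Ly6c2, which shares reads with a close copy, was the 1 member of these that passed over all genes (log2 −0.47 ± 0.12, edgeR adjusted p = 0.048). Adjusted over the list alone 2 monocyte and 2 eosinophil markers fell. These FAT1 libraries also had the higher Rn7s and lower protein-coding shares. The lists of MHC class II (17 genes, median 0.08, camera adjusted p = 0.73) and costimulation (18 genes, 0.06, 0.752) did not pass, and 0 of their genes differed, also adjusted over the list alone. H2-Ab1 (log2 0.28, 95% interval −0.05 to 0.61), Cd74 (0.26, −0.11 to 0.63), H2-K1 (−0.07, −0.36 to 0.23), Cd86 (0.31, 0.03 to 0.60) and Bcl2 (−0.04, −0.42 to 0.35) did not pass. Neither did Cd80, Cd40, Ccr7, Bcl2l1, Bax, Alox5, Ptgs2, Fads2 and Il10 (edgeR adjusted p of 0.17 to 0.98 over these 14 genes). Il12b had 0 counts in WT marrow and too few in FAT1 for a fold.

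The count of 387 depended on single libraries and on the scale. It was 210, 160 and 106 without WT 1, 2 and 3, and 81 and 216 without FAT1 1 and 3. Of the 25 named genes past the threshold 11 kept their call whichever 1 library was left out, among them Mid1, Acod1, Tnfaip3, Pira2, Clec2d, Cd300lb, Nfkbia and Bcl2l11. DESeq2 gave 754 genes (430 higher, 324 lower), and limma on log2(TPM + 1), where the median of all genes shifted by −0.11, gave 859 (73 higher, 786 lower).

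**Figure D2:**
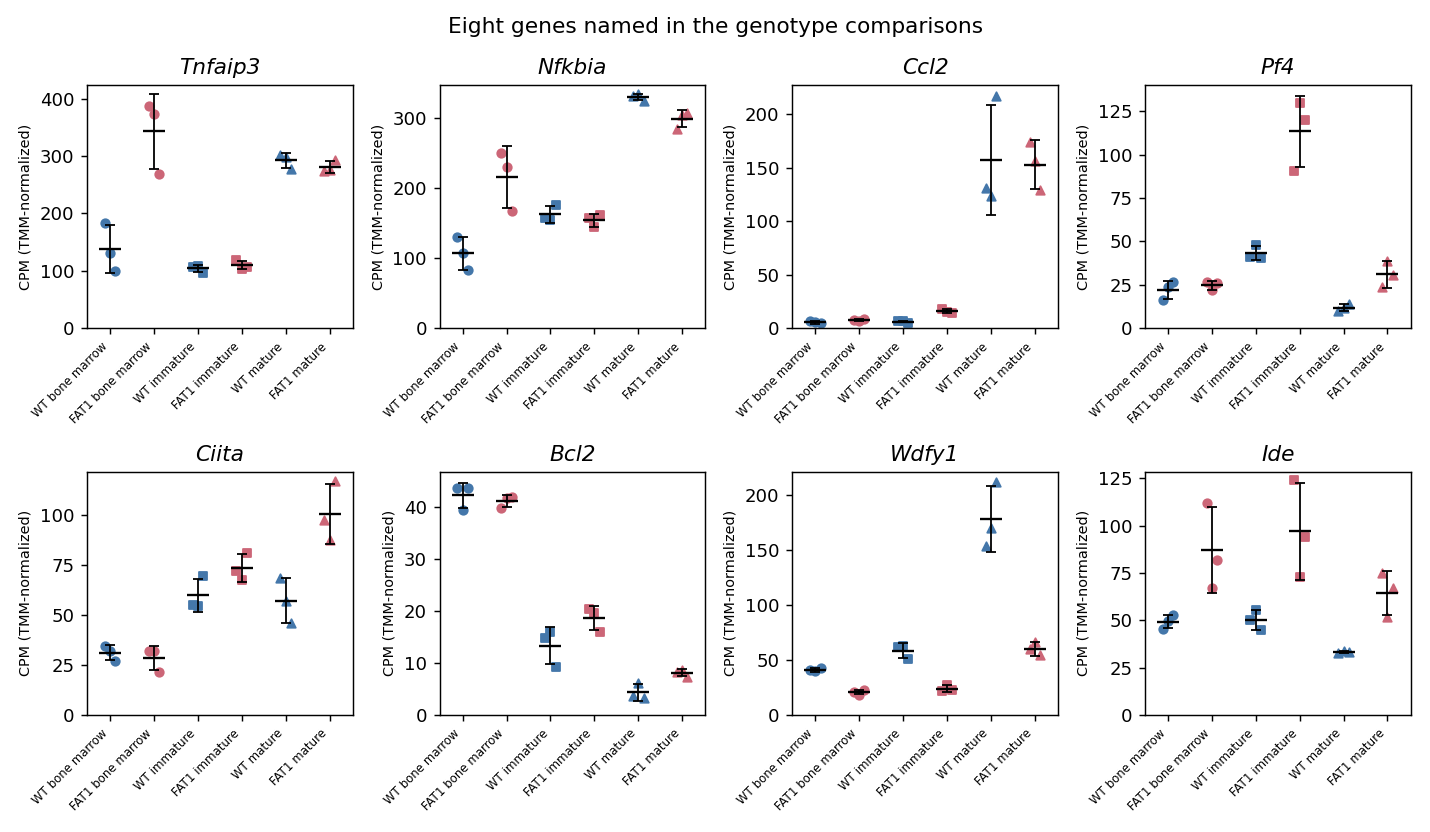
CPM of selected genes in each of the 18 libraries, with points for libraries and the group means marked. Tnfaip3 averaged 138 CPM in WT and 343 in FAT1 marrow, and Wdfy1 178 CPM in WT and 60.3 in FAT1 mature cells.

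In immature BMDCs fewer genes differed between genotypes, 43 higher and 26 lower in FAT1, 69 in all. Ccl2, a chemokine that draws monocytes, rose from 6.16 ± 0.73 to 15.8 ± 1.9 CPM (log2 1.35 ± 0.21, edgeR adjusted p = 0.0041). The platelet chemokine genes Pf4 (43.2 ± 4.1 to 114 ± 21 CPM, log2 1.39 ± 0.19) and Ppbp (6.92 ± 1.8 to 20.4 ± 7.3 CPM, log2 1.56 ± 0.28) rose, with edgeR adjusted p of 0.0014 and 0.014. The serotonin transporter gene Slc6a4 (18.6 ± 0.54 to 8.45 ± 1.1 CPM, log2 −1.14 ± 0.18), the protease gene Ctsk (log2 −1.12 ± 0.21) and Fstl1 (log2 −1.28 ± 0.22) fell, with edgeR adjusted p of 0.0041 to 0.02. Lrmda (0.903 ± 0.2 to 10.6 ± 0.64 CPM, log2 3.54 ± 0.19, edgeR adjusted p = 1.9e-08), Mid1 (log2 3.34 ± 0.46, edgeR adjusted p = 0.0015) and the receptor gene Adgrg3 (log2 1.36 ± 0.28, edgeR adjusted p = 0.042) also rose. Ifi208, of the interferon-inducible p200 family, had 1 count over the WT libraries and 7.55 ± 6.6 CPM in FAT1, a ratio of 492 (95% interval 88 to 19500) that is uncertain among its close copies.

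Inflammatory cytokine genes were higher as a set. Of 22 tested, Ccl2 rose and 21 did not pass, 7 rose and 1 fell adjusted over the list alone, and the median was 0.53 (camera adjusted p = 7.01e-06; adjusted p = 0.161 with an estimated correlation). The 24 cell cycle genes had a median of 0.53 (camera adjusted p = 3.48e-16; adjusted p = 0.259 with an estimated correlation). Of these Ccne2, a cyclin of entry into S phase, rose (2.29 ± 0.78 to 4.58 ± 0.55 CPM, log2 0.99 ± 0.19, edgeR adjusted p = 0.028), and 16 rose adjusted over the list alone. MHC class II genes had a median of 0.15 with 0 of 17 past the threshold and 1 up adjusted over the list alone (camera adjusted p = 0.0289; adjusted p = 0.656 with an estimated correlation). PPAR targets had a median of −0.10 with 0 of 23 past the threshold, also adjusted over the list alone (camera adjusted p = 0.0121; adjusted p = 0.331 with an estimated correlation). The call of class II ended without WT 1 (0.0955), FAT1 1 (0.0609) or FAT1 3 (0.0674), and that of PPAR targets without WT 2 (0.0926) or FAT1 2 (0.127).

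Markers of B cells (15 genes, 0 past the threshold, median 0.51, or 0.49 with genes at 0 counts put at their bound), mast cells and basophils (7 genes, 0 past the threshold, median 0.63) and megakaryocytes (12 genes, Pf4 and Ppbp up, median 0.09) were higher in the same FAT1 libraries. Adjusted over the list alone, 0, 1 and 2 of them rose. Their camera adjusted p were 0.0126, 0.00123 and 0.0474 (adjusted p = 0.486, 0.268 and 0.538 with an estimated correlation). The B cell call ended without FAT1 1 (0.0892) or FAT1 2 (0.0749), and the megakaryocyte call without WT 1 (0.218), WT 3 (0.0674) or FAT1 3 (0.262). Lists that did not pass were MHC class I (21 genes, median 0.02, camera adjusted p = 0.694), costimulation (18, 0.02, 0.808), anti-apoptotic genes (15, median −0.04 and mean 0.08, 0.578), pro-apoptotic genes (23, −0.07, 0.343) and eicosanoid synthesis (19, 0.07, 0.272). In these 0 genes differed, and adjusted over the list alone 2 eicosanoid genes rose. H2-Ab1 (log2 0.13, 95% interval −0.20 to 0.45), Cd74 (0.15, −0.22 to 0.51), H2-K1 (−0.16, −0.45 to 0.14), Cd80 (0.23, −0.10 to 0.56), Cd86 (0.12, −0.14 to 0.37), Bcl2 (0.48, 0.08 to 0.89), Il10 (0.82, 0.03 to 1.60) and Alox5 (0.68, 0.23 to 1.10) did not pass. Neither did Cd40, Ccr7, Il12b, Bcl2l1, Bax, Ptgs2 and Fads2 (edgeR adjusted p of 0.28 to 1 over these 15 genes). The count of 69 was 39 without WT 1 and 44 and 46 without WT 2 and 3. Of the 15 named genes past the threshold, 7 kept their call whichever 1 library was left out. It was 173 by DESeq2 and 142 without a filter on low counts, and 26 higher and 32 lower on TPM.

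In mature BMDCs, 134 genes were higher and 281 lower in FAT1. The neutrophil chemokine gene Cxcl2 rose from 19.8 ± 1.1 to 53.2 ± 23 CPM (log2 1.43 ± 0.22, edgeR adjusted p = 0.0031), and Cxcl3 from 37.6 ± 16 to 94.1 ± 49 CPM (log2 1.33 ± 0.31, edgeR adjusted p = 0.037). Mki67, a marker of cycling cells, rose from 50.4 ± 9.5 to 90.8 ± 1 CPM (log2 0.85 ± 0.14, edgeR adjusted p = 0.0068). The lysozyme gene Lyz2 fell from 10500 ± 2100 in WT to 6050 ± 370 CPM in FAT1 (log2 −0.80 ± 0.16, edgeR adjusted p = 0.019) and the efferocytosis receptor gene Axl from 1040 ± 270 to 619 ± 59 CPM (log2 −0.75 ± 0.15, edgeR adjusted p = 0.017). The carbonic anhydrase gene Car4 (log2 −2.50 ± 0.32), the ribonuclease gene Ear2 (log2 −1.91 ± 0.26), which has close copies, and the protein S gene Pros1 (log2 −1.47 ± 0.25) fell, with edgeR adjusted p of 0.001 to 0.0075. Wdfy1, a gene known to differ between C57BL/6 substrains, fell (178 ± 30 to 60.3 ± 6.2 CPM, log2 −1.56 ± 0.13, edgeR adjusted p = 2e-06). Ifi208 (1.28 ± 0.18 to 274 ± 84 CPM, log2 7.75 ± 0.58), Mid1 (log2 3.56 ± 0.44) and Lrmda (log2 3.04 ± 0.18) rose, with edgeR adjusted p of 7.2e-08 to 0.00044.

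Presentation genes did not move as 1 group. Ciita, the master regulator of MHC class II, rose from 57.2 ± 11 CPM to 101 ± 15 (log2 0.81 ± 0.17, edgeR adjusted p = 0.024), while the class II protease gene Ctss fell (log2 −0.59 ± 0.15, edgeR adjusted p = 0.048). The class II list did not pass (17 genes, 1 up and 1 down, 4 and 2 adjusted over the list alone, median 0.09, camera adjusted p = 0.255). Neither did costimulation (18 genes, Cd48 down at log2 −0.47 ± 0.11, 1 up and 1 down adjusted over the list alone, median 0.00, camera adjusted p = 0.74). The MHC class I list was lower, with a median of −0.29 and 0 of 21 genes past the threshold, but 10 down adjusted over the list alone (camera adjusted p = 8.39e-07; adjusted p = 0.3 with an estimated correlation). Uptake receptors fell in 3 of 20 genes, Axl, Clec4a2 (log2 −0.63 ± 0.14) and Cd68 (log2 −0.61 ± 0.13), and in 9 adjusted over the list alone (median −0.39, camera adjusted p = 0.00084; adjusted p = 0.351 with an estimated correlation).

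The 24 cell cycle genes had a median of 0.54, with Mki67, Ccnb1 (log2 0.96 ± 0.22) and Aurkb (log2 0.59 ± 0.13) up, and 12 up adjusted over the list alone (camera adjusted p = 2.64e-07; adjusted p = 0.379 with an estimated correlation). Of apoptosis genes, the survival gene Bcl2 rose from 4.37 ± 1.6 to 8.08 ± 0.68 CPM (log2 0.87 ± 0.22, edgeR adjusted p = 0.049), while the pro-apoptotic gene Casp8 fell (log2 −0.40 ± 0.10, edgeR adjusted p = 0.048). The pro-apoptotic list (23 genes, 0 up and 2 down, 1 and 7 adjusted over the list alone, median −0.14) did not pass, nor did the anti-apoptotic list (15 genes, 1 up, 2 adjusted over the list alone, median 0.02), with camera adjusted p of 0.0716 and 0.596. Cytokine genes went both ways (22 genes, Cxcl2 and Cxcl3 up, Cxcl11 down at log2 −0.84 ± 0.20, 3 up and 6 down adjusted over the list alone, median −0.04, camera adjusted p = 0.766). Lower lists with 0 genes past the threshold were the type I interferon response (23 genes, median −0.43), oxidative phosphorylation (25, −0.11, 1 up adjusted over the list alone) and glycolysis (18, −0.18). Their camera adjusted p were 0.0126, 0.026 and 0.0208 (adjusted p = 0.777, 0.724 and 0.665 with an estimated correlation). Eicosanoid synthesis did not pass (19 genes, 0 past the threshold, median −0.02 and mean 0.14, camera adjusted p = 0.715).

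Markers of other cells moved in the same libraries. Neutrophil markers were higher (17 genes, median 0.87, with Gfi1 up at log2 1.39 ± 0.31 and Cebpe at 1.01 ± 0.24, and 4 up adjusted over the list alone). So were those of conventional DCs (13 genes, median 0.53, or 0.40 with genes at 0 counts at their bound, with Cd24a up at log2 0.78 ± 0.18), B cells (15 genes, median 0.70, 0 past the threshold) and mast cells (7 genes, median 1.04, Mcpt8 up and Hdc down). Monocyte markers were lower (16 genes, median −0.36, Lyz2 and Cd68 down). Over these 5 lists camera adjusted p were 3.19e-06 to 0.0287, and adjusted p = 0.318 to 0.538 with an estimated correlation. Adjusted over the list alone, the counts were 2 up for conventional DCs, 0 for B cells, 3 up and 1 down for mast cells and 2 down for monocytes. The third mature WT library was itself low in neutrophil, B cell and conventional DC markers. Against the lower of the other mature WT libraries its mean log2 difference was −0.619 (SE 0.2) for neutrophil, −1.15 (SE 0.33) for B cell and −0.826 (SE 0.32) for conventional DC markers. Mast cell markers were not clearly low in it (−0.46, SE 0.35). Monocyte markers were not low, at 0.326 (SE 0.077) against the lower and 0.0603 (SE 0.121) against the higher library. Of these markers 10 of 16 were above both libraries. The SE of these marker means are over the genes of a list, taken as independent, and measure no spread between animals. T and NK markers (15 genes, median 0.91, or 0.00 with genes at 0 counts at their bound) did not pass (camera adjusted p = 0.0874). H2-K1 (log2 −0.46, 95% interval −0.76 to −0.17, edgeR adjusted p = 0.067), Cd80 (0.48, 0.16 to 0.80, edgeR adjusted p = 0.08), H2-Ab1 (0.11, −0.21 to 0.44) and Cd74 (0.09, −0.28 to 0.45) did not pass. Neither did Cd86, Cd40, Ccr7, Il12b, Il10, Bcl2l1, Bax, Alox5, Ptgs2 and Fads2 (edgeR adjusted p of 0.067 to 0.89 over these 14 genes).

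Without the third mature WT library 97 genes differed, 92 of them shared. Of the 32 named genes past the threshold 8 kept their call whichever 1 library was left out, and 27 lost it when edgeR was run on mature libraries alone. Without the third mature WT library 19 lost it, among them Ciita, Ctss, Cd48, Cxcl11, Bcl2, Casp8, Clec4a2, Cd68, Ccnb1, Aurkb, Cd24a, Gfi1, Mcpt8 and Hdc. So did the calls of interferon (camera adjusted p = 0.116), oxidative phosphorylation (0.065), glycolysis (0.289) and B cells (0.11). Calls also ended without WT 1 for oxidative phosphorylation (0.254), without FAT1 1 for oxidative phosphorylation (0.0544), conventional DCs (0.0504) and B cells (0.0625), without FAT1 2 for oxidative phosphorylation (0.123) and B cells (0.114), and without FAT1 3 for interferon (0.134) and monocytes (0.0681). The count was 1121 and 681 without WT 1 and 2, 104 and 51 without FAT1 1 and 3, 1429 by DESeq2, 1077 with no filter, 157 on TPM and 12 when edgeR was run on mature libraries alone.

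**Figure D3:**
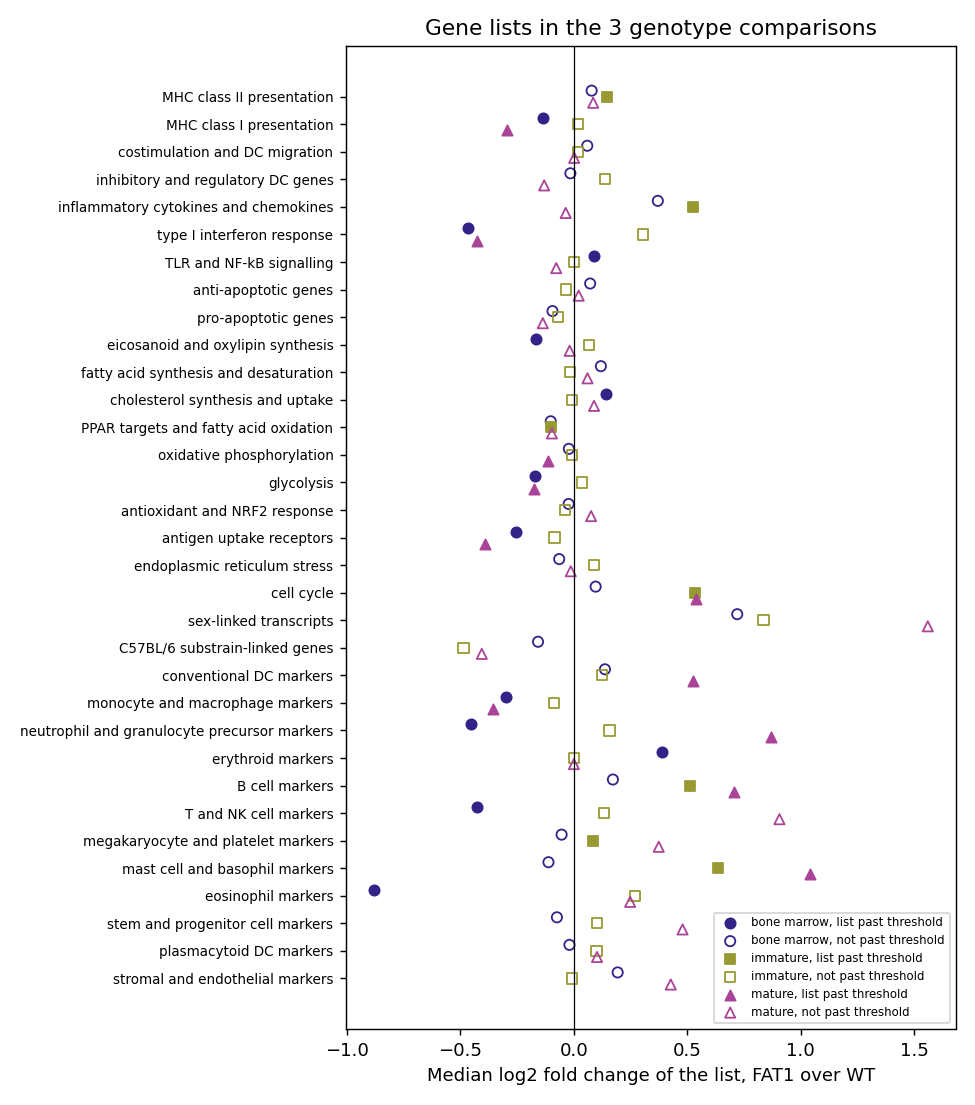
Median log2 fold change of each list between FAT1 and WT in bone marrow, immature and mature cells, with filled points for a camera adjusted p under 0.05. Of the marker lists, erythroid markers were highest in bone marrow at 0.39, and neutrophil markers went from −0.45 in bone marrow to 0.87 in mature cells.

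At all 3 stages 29 genes differed in 1 direction, 19 higher and 10 lower in FAT1. They include Lrmda (mm10 chr14 22019712 to 23056085), Mid1 (chrX 169685199 to 170005736), Ide (chr19 37268743 to 37337852), Wwc2, Cd28 and Nbea, all higher, and Wdfy1 (chr1 79702262 to 79776143), Dynlt1b (chr17 6430112 to 6436296) and Pcyox1, all lower. The rest are predicted or clone-named genes, pseudogenes and the histone gene Hist1h4m. Of these 8 lie on chromosome 14, most of them in 1 segment. Gm47283, which the annotation puts on the Y chromosome, rose as well. Of the 29, 15 had fractional counts in most libraries, which marks reads divided between genes, and 4 had counts identical to those of another gene. Calls at 2 stages overlapped by 21 genes up and 10 down between bone marrow and immature cells (0.611 and 0.231 for independent lists). They overlapped by 22 and 25 between bone marrow and mature cells (1.91 and 2.5), and by 27 and 18 between immature and mature cells (0.344 and 0.436), with 3, 5 and 0 genes opposite. Over all genes, most of them not called, the log2 fold changes correlated weakly, with r = 0.217, 0.196 and 0.338 (rho 0.0586, 0.122 and 0.237). The stages share animals but no libraries. Wdfy1, lower at each stage, is 1 of the 4 substrain genes. Of the others Nnt, which makes the mitochondrial transhydrogenase and is defective in one C57BL/6 substrain, was at 25.5 ± 5.9 CPM in WT and 8.68 ± 4.9 in FAT1 immature cells (log2 −1.55 ± 0.29, edgeR adjusted p = 0.021). In bone marrow, where it did not pass over all genes, Nnt was at 49.3 to 52.9 CPM in WT and 21.2 to 27.2 in FAT1. In mature cells it was at 9.26 to 13.3 CPM in WT and 3.26 to 6.44 in FAT1. Ide rose at each stage (log2 0.83 to 0.95, edgeR adjusted p of 0.0202 to 0.03), and Entpd4, which has a close copy, in bone marrow (log2 0.68 ± 0.11, edgeR adjusted p = 0.0049). As a set of 4 these genes did not pass, with camera adjusted p of 0.981 in bone marrow (2 up, 1 down; 2 and 2 adjusted over the list alone) and 0.304 in immature cells (1 up, 2 down; 2 and 2 adjusted over the list alone). The 2 tested sex-linked transcripts had a median of 0.72 in bone marrow, 0.84 in immature and 1.56 in mature cells, with 0 past the threshold and 1, 0 and 1 up adjusted over the list alone. The list did not pass (camera adjusted p = 0.0556, 0.313 and 0.363). Xist was at 1230 to 2320 CPM in the 6 groups, and the Y-linked genes of the list had 0 counts.

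Culture of bone marrow into immature BMDCs changed most of the transcriptome in both genotypes, with 6214 genes up and 6157 down in WT and 6261 up and 6397 down in FAT1. Gpnmb, a glycoprotein of macrophages and DCs, rose from 0.509 ± 0.35 to 6010 ± 640 CPM in WT (log2 13.50 ± 0.36) and from 0.304 ± 0.18 to 6770 ± 360 in FAT1 (log2 14.50 ± 0.38), each at an edgeR adjusted p of 1.6e-14. Mmp12, the macrophage elastase, rose from 0.103 ± 0.091 to 2310 ± 1100 CPM in WT (log2 14.30 ± 0.73, edgeR adjusted p = 1.4e-10) and at least 46700-fold in FAT1, where marrow had 0 counts. The chemokine gene Ccl22 reached 889 ± 150 and 886 ± 110 CPM. The red cell gene Slc4a1 fell from 1430 ± 260 CPM in WT and 1960 ± 460 in FAT1 marrow to 0 counts in both, at least 32100-fold and 44400-fold lower. Il12b, the p40 subunit of IL-12 and IL-23, rose at least 607-fold to 29.3 ± 3.3 CPM in WT.

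The culture step raised all 21 MHC class I genes (median 1.18 in WT and 1.34 in FAT1) and all 21 cholesterol genes (1.34 and 1.31) in both genotypes, for example B2m (361 ± 12 to 1770 ± 190 CPM in WT) and Hmgcs1 (23.4 ± 3.3 to 118 ± 11). In costimulation and migration 17 of 18 genes rose and 1 fell in each genotype (medians 2.58 and 2.42), led by Ccl22 and the actin bundler Fscn1 (1.49 ± 0.17 to 686 ± 98 CPM in WT). MHC class II rose in 11 of 17 genes in WT and 12 in FAT1, with 1 down in each (1.82 and 1.87), Ctss going from 95.5 ± 5.5 to 3810 ± 410 CPM in WT. Uptake receptors rose in 17 of 20 genes and fell in 3 in each genotype (2.58 and 2.87). TLR and NF-kB genes rose in 22 of 25 and fell in 2 and 3 (1.52 and 1.20), and PPAR targets rose in 20 of 23 (0.86 and 1.01), led by the lipid carrier Fabp5 (8.13 ± 0.22 to 904 ± 110 CPM in WT). Inhibitory DC genes rose in 12 of 18 and fell in 2 in WT, and 14 and 3 in FAT1 (1.24 and 1.38), led by Ido1 in both, with Cd274 (PD-L1) going from 9.99 ± 0.71 to 266 ± 21 CPM in WT. Antioxidant genes rose in 15 of 20 in each, with 3 and 4 down (1.11 and 1.26), Srxn1 going from 6.11 ± 1.5 to 160 ± 26 CPM in WT. Over these 9 lists camera adjusted p were 1.33e-06 to 0.0117, and adjusted p = 0.202 to 0.486 with an estimated correlation.

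Interferon genes rose in 15 of 23 in WT and 19 in FAT1, with 2 and 1 down (medians 1.24 and 1.74, or 1.12 and 1.73 at bounds). Glycolysis rose in 13 and 14 of 18, with 3 and 2 down (0.92 and 1.05). Oxidative phosphorylation rose in 16 of 25 in each, with 3 and 4 down (0.39 and 0.46). Both apoptosis lists rose, the pro-apoptotic list with 16 up and 3 down of 23 in WT and 15 and 1 in FAT1 (0.85 and 0.82), including Bax (18.4 ± 0.53 to 61.2 ± 1.2 CPM in WT). The anti-apoptotic list had 11 of 15 up in each and 3 and 4 down (0.93 and 0.82). In the latter Bcl2a1b and its copies led the rise, and Birc5, a survival gene of dividing cells, fell (76.3 ± 4.3 to 3.33 ± 0.32 CPM in WT). For these 5 lists camera adjusted p were 0.00263 to 0.0426, and adjusted p = 0.238 to 0.828 with an estimated correlation. The interferon call in WT ended without WT marrow 2 (0.0517) or immature 2 (0.0893). That of oxidative phosphorylation ended without WT marrow 1 or 3 (0.057, 0.0528) or immature 2 (0.0636) in WT, and without marrow 2 (0.0632) or immature 3 (0.0605) in FAT1. Cytokines (22 genes; 7 up and 7 down in WT, 10 and 7 in FAT1), eicosanoids (19; 8 and 7, 9 and 7; medians 0.18 and 0.33 with means of −0.65 and −0.22), fatty acid synthesis (19; 10 and 3, 8 and 6), endoplasmic reticulum stress (18; 11 and 3, 10 and 5) and conventional DC markers (13; 5 and 4 in each, in WT with a median of −0.05 and a mean of 0.25) did not pass, with camera adjusted p of 0.135 to 0.951.

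Cell cycle genes and markers of 9 cell types fell in culture. All 24 cell cycle genes fell in both genotypes (medians −3.48 and −3.05), Mki67 from 1610 ± 58 to 61.5 ± 4.3 CPM in WT and from 2040 ± 410 to 91.8 ± 3.8 in FAT1. All 14 erythroid markers fell (median −10.90 and −11.20 with the 10 and 11 genes at 0 counts at their bound), and so did all 15 T and NK and all 7 mast cell markers. All 17 neutrophil markers fell but for 1 that rose in FAT1, with Mpo at 821 ± 150 CPM in WT marrow and 0.935 ± 0.35 after culture. Further markers fell in 13 and 12 of 15 for B cells with 1 up and in 10 of 12 for megakaryocytes with 2 up. They fell in 10 of 11 for stem cells, in 9 of 10 for plasmacytoid DCs, and in 9 and 10 of 11 for stromal cells. Over these 10 lists camera adjusted p were 9.38e-11 to 0.00453, and adjusted p = 0.0791 to 0.338 with an estimated correlation. Monocyte markers rose in 13 of 16 and fell in 2 (medians 2.78 and 3.24, camera adjusted p = 0.000836 and 0.000479; adjusted p = 0.389 and 0.364 with an estimated correlation), Adgre1 (F4/80) going from 31 ± 1.5 to 412 ± 30 CPM in WT. Eosinophil markers did not pass (9 genes; 6 down and 2 up, 5 and 2; camera adjusted p = 0.21 and 0.451). Adjusted over the list alone these counts were as given, but for 10 plasmacytoid DC markers down in WT and 10 eicosanoid genes up in FAT1. On TPM, where the median of all genes shifted by 0.25 and 0.31, 8066 genes rose and 3882 fell in WT and 8551 and 3598 in FAT1.

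Maturation raised cytokine and interferon genes most. With it 4490 genes rose and 4559 fell in WT, and 3999 rose and 4011 fell in FAT1. The inducible nitric oxide synthase gene Nos2 rose from 0.0894 ± 0.047 to 362 ± 92 CPM in WT (log2 11.90 ± 0.33, edgeR adjusted p = 3.4e-13) and from 0.188 ± 0.13 to 354 ± 46 in FAT1 (log2 10.90 ± 0.31, edgeR adjusted p = 6.5e-13). Cxcl10 rose from 5.36 ± 2 to 1090 ± 190 CPM in WT and from 8.99 ± 6 to 738 ± 180 in FAT1. Fn1, the fibronectin gene, fell from 778 ± 87 to 15.1 ± 4.8 and from 645 ± 140 to 16.6 ± 4 CPM. The mannose receptor gene Mrc1 fell from 276 ± 32 to 29.4 ± 6.3 and from 292 ± 11 to 27.8 ± 1.1 CPM, with edgeR adjusted p of 3e-11 to 8.2e-11 for these 4 values. The costimulatory gene Cd86 rose from 35.2 ± 4.3 to 226 ± 19 and from 38.1 ± 3.9 to 212 ± 13 CPM.

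All 23 interferon genes rose in both genotypes (medians 4.27 and 3.59), with the viperin gene Rsad2 going from 64.3 ± 33 to 7840 ± 2100 CPM in WT and from 104 ± 87 to 5790 ± 690 in FAT1. Cytokines rose in 19 of 22 in each, with 1 down in WT (3.30 and 2.97). MHC class I rose in 17 of 21 in WT with 1 down and in 16 in FAT1 with 2 down (1.85 and 1.47), with Tap1 going from 119 ± 9.3 to 651 ± 24 and from 133 ± 23 to 550 ± 35 CPM. TLR and NF-kB genes rose in 19 and 18 of 25 with 1 down (1.02 and 0.81), and glycolysis in 16 and 15 of 18 with 1 down (0.84 and 0.60). Costimulation rose in 10 and 11 of 18 with 2 down (0.73 and 0.74), and inhibitory genes in 13 and 12 of 18 with 4 down (1.39 and 1.34), with Socs3 going from 7.91 ± 0.88 to 277 ± 78 CPM in WT. Pro-apoptotic genes rose in 14 and 13 of 23 with 4 down (0.47 and 0.51), with Bak1 going from 105 ± 4.5 to 371 ± 48 CPM in WT. Over these 8 lists camera adjusted p were 5.71e-13 to 0.00538, and adjusted p = 0.0534 to 0.466 with an estimated correlation. Anti-apoptotic genes rose in 10 and 9 of 15 with 2 down (0.54 and 0.53), led by Cflar (177 ± 6.1 to 858 ± 140 CPM in WT), while Bcl2 fell from 13.3 ± 3.6 to 4.37 ± 1.6 and from 18.6 ± 2.3 to 8.08 ± 0.68 CPM. Their camera adjusted p were 0.0541 in WT, 0.0496 with the animal as a block, and 0.0239 in FAT1 (adjusted p = 0.288 and 0.259 with an estimated correlation).

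Lipid synthesis fell with maturation. Cholesterol genes fell in 18 of 21 in WT and 19 in FAT1 with 1 up (medians −1.69 and −1.61), with Fdps, an enzyme of the mevalonate pathway, going from 28.9 ± 3.7 to 4.35 ± 1.5 and from 28.9 ± 1.5 to 4.72 ± 1.2 CPM. Fatty acid genes fell in 12 and 11 of 19 with 3 up (−0.81 and −0.66), with the desaturase gene Fads2 going from 16.1 ± 1.8 to 2.06 ± 1.3 and from 16 ± 2.5 to 3 ± 0.44 CPM. Fasn fell from 89.7 ± 12 to 14.6 ± 5.2 CPM in WT. PPAR targets fell in 15 and 14 of 23 with 4 and 2 up (−0.69 and −0.56), with Cd36 going from 614 ± 280 to 171 ± 55 CPM in WT. Camera adjusted p for these 3 lists were 2.03e-09 to 0.00599, and adjusted p = 0.241 to 0.369 with an estimated correlation. Monocyte markers fell in 10 and 9 of 16 with 5 and 3 up (−0.83 and −0.74). They passed in FAT1 (camera adjusted p = 0.0465; adjusted p = 0.658 with an estimated correlation) but not in WT (0.372), and the call ended without immature FAT1 1 or 2 (0.0502, 0.0984) or mature FAT1 3 (0.0727).

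Eicosanoid genes went both ways (19 genes; 6 up and 7 down in WT, 4 and 8 in FAT1), with the prostaglandin synthase genes Ptges (5.94 ± 0.9 to 147 ± 34 CPM) and Ptgs2 (2.66 ± 0.48 to 34.1 ± 6.1) up in WT. Other lists that did not pass were MHC class II (17; 8 and 1, 7 and 1), uptake receptors (20; 8 and 10, 6 and 11), antioxidant genes (20; 7 and 9, 6 and 8) and endoplasmic reticulum stress (18; 8 and 6, 7 and 7, in FAT1 with a median of −0.04 and a mean of 0.35). The same held for oxidative phosphorylation (25; 5 and 6, 2 and 6), the cell cycle (24; 3 and 3, 1 and 3), neutrophil markers (17; 1 and 8, 3 and 4) and sex-linked transcripts (2; 0 and 1 in each). Camera adjusted p over these 9 lists were 0.0918 to 0.932. Adjusted over the list alone, counts moved by 1 or 2 genes, for example to 20 up and 2 down for TLR and NF-kB genes and 9 down for eicosanoids in WT and 13 up for costimulation in FAT1. On TPM 2686 genes rose and 5495 fell in WT, where the median of all genes shifted by −0.13, and 2622 and 4068 in FAT1.

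**Figure D4:**
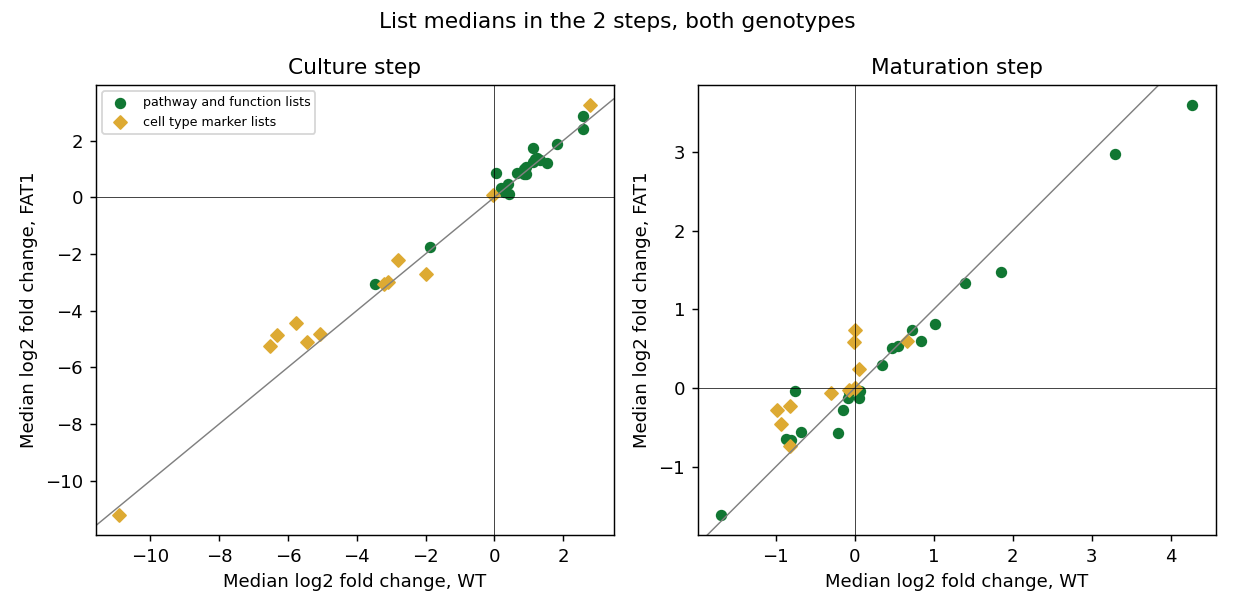
Median log2 fold change of each list with culture and with maturation in WT and FAT1, with genes at 0 counts put at their bound. Erythroid markers lie lowest with culture, at −10.90 in WT and −11.20 in FAT1, and interferon genes highest with maturation, at 4.27 and 3.59.

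The steps were alike in WT and FAT1 across genes, which are not independent replicates. The log2 fold changes correlated with r = 0.962 (rho 0.957) for culture and r = 0.85 (rho 0.836) for maturation. In culture 5653 genes rose and 5658 fell in both genotypes (2320 and 2350 for independent lists) and 15 went opposite ways, and in maturation 3609 and 3489 (1070 and 1090), with 2 opposite.

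The interaction test asked where the steps themselves differed between genotypes. With culture 27 genes did, 12 with a higher and 15 with a lower log2 fold change in FAT1 than in WT. Pira2 went from 57.9 ± 0.66 to 98.7 ± 6.2 CPM in WT and from 24 ± 1.6 to 186 ± 6.7 in FAT1 (log2 difference 2.18 ± 0.20, edgeR adjusted p = 0.00012). The monocyte antigen gene Ly6c2 went from 251 ± 25 to 47.7 ± 6.8 and from 181 ± 18 to 81.7 ± 5.4 (1.25 ± 0.17, edgeR adjusted p = 0.0078). Both share reads with close copies. Ifrd1, a transcriptional coregulator, went from 54.2 ± 5.9 to 74.1 ± 2.6 in WT and from 130 ± 20 to 75.6 ± 1.5 in FAT1 (−1.23 ± 0.14, edgeR adjusted p = 0.0014). Tnfaip3 (−1.24 ± 0.23) and Nfkbia (−1.10 ± 0.20), higher in FAT1 marrow, were at 104 ± 6.5 and 163 ± 11 CPM in WT and 110 ± 7 and 154 ± 9.2 in FAT1 immature cells, with edgeR adjusted p of 0.041 and 0.04. Dab2ip (1.73 ± 0.33), Cst7 (1.32 ± 0.24), Zfp87 (0.95 ± 0.18), Rasgrp4 (0.87 ± 0.16), Per1 (−0.84 ± 0.13), Rabgef1 (−0.79 ± 0.12) and Klf9 (−0.74 ± 0.13) also passed, with edgeR adjusted p of 0.01 to 0.041. With the animal as a block 7 genes passed, 4 of them shared, and among the 12 named genes the calls other than Pira2, Ly6c2 and Ifrd1 ended (edgeR adjusted p of 0.053 to 0.079). The count of 27 was 11 and 9 without WT marrow 2 and 3, 8 without FAT1 marrow 1, 9, 9 and 12 without immature WT 1, 2 and 3, and 7, 10 and 14 without immature FAT1 1, 2 and 3. It was 245 by DESeq2, 91 with no filter, 147 with only the groups compared, 550 by voom with quality weights and, on TPM, 59 higher and 11 lower.

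With maturation 0 genes passed in edgeR, 1378 had an unadjusted p under 0.05, and DESeq2 called 9, limma on TPM 5 and voom with quality weights 2. The 6 genes with the smallest p, none past the threshold, were AA467197 (log2 difference −1.06), Slc16a6 (1.04), Rtl10 (3.02), Ccl2 (−1.39), Qtrt2 (0.88) and Ccl3 (−1.10), with edgeR adjusted p of 0.34 to 0.51. As sets, the interferon genes (median −0.73), MHC class I (−0.30) and cytokines (−0.57) were raised less by maturation in FAT1 than in WT, with camera adjusted p of 0.00112, 8.47e-08 and 0.00213 (adjusted p = 0.724, 0.269 and 0.259 with an estimated correlation). Adjusted over the list alone, 4 cytokine genes had the smaller change and 0 genes of the other lists. The interferon call ended without immature FAT1 2 (0.612). The third mature FAT1 library stood lowest on an axis of maturation taken from the FAT1 libraries, at 0.774 against 0.859 to 0.904 in the other mature libraries. These positions are measured from the immature WT mean, not from the animal's own immature library. It also had the least Cxcl10 (535 CPM, against 876 and 804 in FAT1). From its own immature library the median log2 change of that animal was 4.14 for interferon, against 3.65 and 2.96 in the other FAT1 animals. It was 3.11 for cytokines (2.72 and 2.57) and 1.46 for MHC class I (1.48 and 1.49). Without the third mature FAT1 library the calls of these 3 lists were kept.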

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

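The tests of the C57BL/6 substrain genes, of another mix of marrow cells and of another mix of dendritic cells and macrophages were chosen only after the results were seen, as was the count of animals given with the lists. Each result here is a step whose change differed between WT and FAT1 by the interaction test.

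With culture 27 genes differed in their step. Pira2 (log2 difference 2.18), Dab2ip (1.73), Cst7 (1.32), Ly6c2 (1.25), Zfp87 (0.952) and Rasgrp4 (0.866) had the higher log2 fold change in FAT1. Tnfaip3 (−1.24), Ifrd1 (−1.23), Nfkbia (−1.10), Per1 (−0.844), Rabgef1 (−0.787) and Klf9 (−0.742) had the lower one. With the animal as a block the calls of 9 of these 12 genes ended, those of Pira2, Ly6c2 and Ifrd1 being kept, and 8 ended leaving out 1 library or another. Tnfaip3, Ifrd1, Nfkbia, Per1, Rabgef1 and Klf9 were higher in FAT1 marrow and did not pass between genotypes after culture.

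As sets, the culture step differed by a median log2 of 0.191 for MHC class I, 0.792 for interferon, 0.219 for eicosanoid synthesis, 0.224 for glycolysis, 0.428 for the cell cycle and −0.102 for cholesterol. Among markers it differed by 0.182 for monocytes, 0.621 for neutrophils, −0.482 for erythroid cells, 0.406 for T and NK cells, 0.711 for mast cells and 0.69 for eosinophils. These 12 lists passed camera, with adjusted p = 0.222 to 0.724 with an estimated correlation. The median change of all 3 FAT1 animals lay beyond those of the WT animals for MHC class I, eicosanoids and the cell cycle, and that of 1 or 2 of the 3 for the other lists. Leaving out 1 library ended the calls of 7 of them. Without immature FAT1 2 that was so for MHC class I (camera adjusted p = 0.0534) and interferon (0.567). It was so for glycolysis without WT marrow 1 (0.0723) or immature WT 3 (0.133), and for monocytes without FAT1 marrow 3 (0.0942) or immature FAT1 2 (0.142). Mast cells lost their call without FAT1 marrow 3 (0.0928), immature WT 1 and 2 (0.08, 0.0941) or immature FAT1 3 (0.105). Eosinophils lost it without WT marrow 1 and 3 (0.0987, 0.0769), FAT1 marrow 1 and 2 (0.142, 0.0531), immature WT 2 (0.0594) or immature FAT1 1 (0.069). Cholesterol lost it without WT marrow 2 and 3 (0.122, 0.0671), FAT1 marrow 2 and 3 (0.284, 0.0716), immature WT 1 and 2 (0.086, 0.186) or immature FAT1 2 and 3 (0.0979, 0.107), and with the block (0.0596). The maturation step differed by −0.295 for MHC class I, −0.572 for cytokines, −0.73 for interferon, −0.127 for TLR and NF-kB genes, −0.173 for glycolysis, −0.224 for uptake, −0.445 for monocyte markers and 0.603 for neutrophil markers (adjusted p = 0.259 to 0.724 with an estimated correlation). All 3 FAT1 animals lay beyond the WT animals for MHC class I, none for glycolysis, and 1 or 2 of the 3 for the others. The call of interferon ended without immature FAT1 2 (camera adjusted p = 0.612), and those of glycolysis (0.0919) and uptake (0.244) without mature WT 3. That of monocytes ended without mature WT 3 (0.065), immature FAT1 2 (0.0652) or mature FAT1 3 (0.0722). That of TLR and NF-kB genes ended without immature WT 1 and 2 (0.0666, 0.13), immature FAT1 3 (0.113), mature WT 1 and 2 (0.117, 0.0556) or mature FAT1 2 (0.106).

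The first pattern weighed is the rise of Tnfaip3, Nfkbia, Nfkbie and Nfkbiz in FAT1 marrow, by a median log2 of 0.853 over these 4 genes, which are those that passed out of a list of 25 with a median of 0.087. Another mix of marrow cells, if a whole marker list follows it, would need that list to rise as much. The largest median rise was 0.39, of erythroid markers, and the highest upper bound of any of the 12 lists was 0.561. That bound comes from the spread over the genes of a list, taken as independent, and not from animals. These values argue against a rise of a whole list as the whole cause of the rise of these 4 genes. Picking the genes that passed sets the bar high, though. A median can hide single members. In the stromal and endothelial list, Col1a1 was at 201 to 372 CPM in FAT1 and 66.8 to 193 in WT marrow. Cxcl12 of that list overlapped, at 82.9 to 132 and 79 to 119 CPM. So a rise of cells that a list covers only in part stays open. Handling of the marrow before lysis may raise such genes. A list of 24 handling and immediate-early genes without NF-kB members had a median of 0.123, with 0 past the threshold in edgeR, 16 above 0 and a camera p of 0.16 (0.472 with an estimated correlation), so that handling and an effect of the transgene cannot be told apart. The list leaves out Nr4a2, a relative of its member Nr4a1. Nr4a2 was at 17.4 to 24.6 CPM in FAT1 marrow and 6.35 to 9.74 in WT marrow. Ccn1, also not on the list, was at 3.47 to 8.32 CPM in FAT1 and 0.651 to 1.32 in WT marrow. So the list does not cover all genes of this kind.

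The second pattern is the 29 genes that differed at all 3 stages. Reads shared between copies may account for part of them, since 15 had fractional counts in most libraries (51.7%, against 13.3% of all tested genes, Fisher exact p = 8.17e-07), while 10 had neither fractional counts nor counts identical to those of another gene. A strain variant in the FAT1 line is the other candidate, since 4 of 4 substrain genes differed at 1 stage or more, against 4.6% of all tested genes (Fisher exact p = 4.45e-06). Wdfy1 and Ide of these are themselves among the 29, and the test was chosen after the calls were seen, so this p is no independent support. A first test of the strain variant asked for neighbouring genes and came out in its favour, with 20 pairs within 1 Mb against a random 95th percentile of 2, and 11 against 1 among the 14 genes without fractional counts, but was set aside because most pairs were copies or overlapping genes. An effect of the transgene on these genes was not tested, and differences of strain and of transgene cannot be parted in this design.

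The third pattern is the genes that differed between genotypes in mature cells, whose fold changes without the third mature WT library were 0.808 of those with all libraries in the median, against 0.904 to 1.1 without any other mature library. In this pattern each SE is from the spread over genes, taken as independent, and measures no spread between animals. The bound set beforehand for excluding the third mature WT library as the cause was 0.8, which 0.808 first read as passing. A demand that it be passed by more than the spread over genes (SE 0.0081) was added after this was seen and leaves the matter open. A maturation weaker on the whole, over the 8010 genes called with maturation in FAT1, is argued against by the position of this library. It was 0.904 on the maturation axis, measured from the immature WT mean. That value lay above 0.862 and 0.872 of its group and 0.774 to 0.868 of the FAT1 libraries. Genes with the largest changes weigh most in that position, and they did not move as 1 group. Rsad2 (10200 against 6420 and 6890 CPM) was higher in this library, but Ccr7 (153 against 830 and 687 CPM), Fscn1 (231 against 1260 and 1280) and Il12b (10.8 against 63.5 and 61) were lower in it. An excess of cells of types other than DCs, monocytes and macrophages is argued against by 0.0129 as the highest mean log2 excess of their marker lists over the higher of both (megakaryocytes), a measure that leans low, so that against the mean of both a small excess stays open for megakaryocytes (0.208, SE 0.16) and eosinophils (−0.0517, SE 0.3), while fewer B cells (−1.15, SE 0.33, against the lower of both) and neutrophils (−0.619, SE 0.2) are not argued against. Another mix of DCs and macrophages stays open, since the costimulation and migration list was lower by a mean log2 of −0.641 (SE 0.222; 14 of 18 genes below both other libraries) and conventional DC markers by −0.826 (SE 0.32; 8 of 13), while the monocyte and macrophage list was not clearly above both (0.0603, SE 0.121; 10 of 16 genes above both).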

How the results depend on the processing

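Voom with quality weights was chosen only after the results were seen, as was camera without the third mature WT library, which is also a planned setting, and the other tests were planned. No single named gene or list that was called changed direction. Of 579 named calls 504 were kept whichever 1 library was left out, 577 by DESeq2, 575 without a filter and 514 on TPM. Most of the 579 belong to the culture and maturation steps. Leaving out 1 library kept 132 of 132 and 129 of 129 calls with culture in WT and FAT1. With maturation it kept 110 of 117 and 103 of 117. Between genotypes it kept only 11 of 25 in bone marrow, 7 of 15 in immature and 8 of 32 in mature cells. For the interaction with culture 4 of 12 were kept. Genes between genotypes in bone marrow (387) were 754 by DESeq2, 859 on TPM and 1705 by voom with quality weights, and 81 to 379 leaving out 1 library. They were 210, 160 and 106 without WT 1, 2 and 3 and 81 and 216 without FAT1 1 and 3. In immature cells (69) they were 173 by DESeq2, 142 without a filter and 404 by voom, and 39 to 49 leaving out 1 library (39, 44 and 46 without WT 1, 2 and 3). In mature cells they were 1429 by DESeq2, 1077 without a filter, 12 with only the groups compared and 157 on TPM, and 51 to 1121 leaving out 1 library (1121, 681 and 97 without WT 1, 2 and 3, 104 and 51 without FAT1 1 and 3). The interaction with culture (27) gave 245 by DESeq2, 91 without a filter, 147 with only the groups compared, 70 on TPM and 550 by voom, and 7 to 30 leaving out 1 library (11 and 9 without WT marrow 2 and 3, 8 without FAT1 marrow 1, 9, 9 and 12 without immature WT 1, 2 and 3, 7, 10 and 14 without immature FAT1 1, 2 and 3). The interaction with maturation (0 in edgeR, 1378 at an unadjusted p under 0.05) gave 9 by DESeq2, 6 without a filter, 5 on TPM and 2 by voom, and 0 to 1 leaving out 1 library (1 without mature FAT1 3). The balance of higher and lower genes did turn. In bone marrow 238 and 149 became 73 and 786 on TPM and 274 and 301 with only the groups compared, and in immature cells 43 and 26 became 26 and 32 on TPM and 197 and 207 by voom. In mature cells 134 and 281 became 9 and 3 with only the groups compared and 30 and 21 without FAT1 3. In the interaction with culture 12 and 15 became 59 and 11 on TPM, 59 and 32 without a filter, 99 and 48 with only the groups compared and 6 and 1 with the block, and more genes were higher without WT marrow 2 or 3, immature WT 1 or 2 or any immature FAT1 library. Total counts for culture and maturation stayed within 1.5 times under each alternative. Their parts did not on TPM, where the lower genes with culture went from 6157 to 3882 in WT and from 6397 to 3598 in FAT1, and the higher genes with maturation from 4490 to 2686 and from 3999 to 2622. The near-even balance of these steps turned under several alternatives, on TPM from 6261 and 6397 to 8551 and 3598 with culture in FAT1. On TPM, Rn7s1 and Rn7s2 took 45.5% to 49.3% of the total in WT marrow and 50.6% to 58.9% in FAT1 marrow. They took 36.1% to 40.4% in immature and 33.4% to 37.2% in mature cells. TPM sum to a fixed total, so a larger share of these genes leaves less for all others. That goes with the direction of the TPM shifts in marrow and with culture, but not with maturation. How far it accounts for the turns on TPM was not tested, and no cause was tested for the others. Fewer libraries lower the power of a test, and depth limits calls of genes near the filter on low counts.

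With the animal as a block, the interaction with culture gave 7 genes, 4 shared with the 27, and the calls of 9 of 12 named genes ended there, of 2 of 117 with maturation in each genotype and of none with culture. Of 124 lists that passed camera, 2 lost their call with the block of their comparison, megakaryocyte markers in immature cells (camera adjusted p = 0.051, median log2 0.09) and cholesterol in the interaction with culture (0.0596, median −0.10), and 2 gained it, sex-linked transcripts in bone marrow (0.0427) and anti-apoptotic genes with maturation in WT (0.0496). Between genotypes the block was the replicate number, with which 291 genes differed between genotypes in bone marrow (276 shared with the 387), 79 in immature cells (66 shared with the 69) and 282 in mature cells (252 shared; 112 higher and 170 lower, against 134 and 281), and 2 of 25, 1 of 15 and 8 of 32 named calls ended. Neither block moved another total by over 1.5 times or changed another call of a list described. All 124 lost their call with an estimated correlation, 34 with fry and 0 without a filter, and 30 when 1 library or another was left out. Between genotypes the numbers of the animals pair nothing, so a block there is only an alternative.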

Other observations

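All tests in this part were planned before the data were examined.

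Each comparison of 3 with 3 libraries has 10 splits, which are too few for a share under 0.05. Every split other than the real one mixes the real groups on both sides. A real difference then becomes spread within groups and holds the count down. So low counts in the other splits were likely beforehand, and they do not measure how many calls arise without a difference. The real split gave 387 genes in bone marrow, 69 in immature cells and 134 higher and 281 lower in mature cells between genotypes, and the highest other split 0, 18 and 0. For culture it gave 12371 genes in WT and 12658 in FAT1, and the highest others 0 and 0. For maturation it gave 9049 and 8010, and the highest others 33 and 1, or 33 and 0 among splits that part the animals in the same way. For the interactions it gave 27 and 0, and the highest others 0 and 0. As many genes as in the real split came from 1 split, the real one, in each case but the interaction with maturation, where 10 of 10 splits gave 0 genes in edgeR (1378 at an unadjusted p under 0.05 in the real split, 9 by DESeq2).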
